A study of Mus musculus with 14 samples.

How the data were processed

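RNA was sequenced from 14 cultures of mouse HPC-LSK lines, which are haematopoietic progenitor lines that resemble the Lin-negative, Sca-1-positive, Kit-positive (LSK) fraction of bone marrow. The lines were wild type (WT) or knockout (KO) for Cdk6, on a C57BL/6N background per the labels, and were either untransformed or transformed with BCR-ABL p210. There were 4 WT untransformed, 3 KO untransformed, 3 WT p210 and 4 KO p210 libraries. Per the labels' protocols, untransformed cells were grown with 12.5 ng/ml IL-6 and 2% SCF and p210 cells without either cytokine. The descriptions of the p210 samples carry the letters SCF, whose meaning the labels do not settle. Transformation and culture medium changed together and cannot be separated. RNA was extracted with a column kit and libraries were made with the SENSE mRNA-Seq kit and read as 50 bp single ends, per the labels' protocols.

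Reads were processed by the authors with Trimmomatic, STAR and featureCounts on GRCm38, per the submitters' processing notes. The versions of Trimmomatic and STAR were not given in the sources used here. The deposited raw counts per gene came from featureCounts 1.5.1 with reverse-stranded counting against GENCODE M13, per the file headers. The deposited TPM values stand beside the counts in each file and were computed by the authors from the same counts, per the file headers and the values. Recomputing TPM from counts and gene lengths gave a largest difference of 0.049, within a tolerance of 0.05. TPM values were not used in any test. The files list 50686 genes, of which 50376 were given a symbol from a GENCODE M21 table, and coordinates are those of the files. Because counting used strand, antisense neighbours were counted apart. Genes with near-identical copies remain uncertain.

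Total counts per library ranged from 20270348 to 50303271, and 3 counts over a group stood for 0.0198 to 0.0369 CPM. Molecular identifiers were not used here, and intervals and floors given for low counts cover counting error only. A fold against a group with no counts was computed against a floor of 3 counts over the group, from the pooled or the mean CPM of the other group, whichever was lower, and a ratio against a group with 1 to 3 counts is of pooled counts and is given with its 95% exact interval.

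Counts were tested with edgeR 4.0.16 under R 4.3.3 by the quasi-likelihood F-test with robust dispersion, TMM scaling and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The filterByExpr defaults (minimum count 10, minimum total 15) left 14512 genes. All 14 libraries entered 1 fit with group as the only term, and 5 contrasts were tested: KO against WT in each state, p210 against untransformed in each genotype, and the interaction of genotype and transformation. Every adjusted p of a gene below comes from this test unless another tool is named. Group values are CPM on TMM-scaled library sizes as mean ± SD, and log2 fold changes are given with their SE. The labels do not say whether replicates of a group were separate cultures of a line or separate derivations, so p-values measure the spread between these samples. That spread was estimated per gene over all groups together, not within the groups compared.

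Design, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Cdk6 in each comparison. It then took the 10 genes per direction (5 for the interaction) with the largest fitted fold changes among those past the threshold that had at least 5 CPM in the higher group, no overlap between the groups (not asked of the interaction) and no predicted-gene name. It also took up to 4 members of each list with the smallest adjusted p, and up to 2 abundant members of lists that did not move. The text names fewer than the rule gives, in the order of the rule. Some genes that the rule gives are not reported here, and counts of named genes and of tests over them include these. Of 28 lists, 26 were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over the lists within a comparison). The lists covered cell cycle and stress programmes, signalling, metabolism, progenitor markers, and markers of other lineages that the cultures could hold. The size given for a list below counts only members that were tested. Among lists with many members not tested, these were 14 of 25 erythroid and 16 of 30 lymphoid genes. They were 12 of 18 dendritic cell and MHC class II genes and 9 of 20 stromal and endothelial markers. The sex-linked and histone lists served as sample checks. All 50 camera calls were lost when the correlation between members was estimated from the data, so each list call in the report carries that second p.

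Descriptions carry a letter and 1 of 2 codes, the first on replicates 1 and 2 of every group and the second on replicates 3 and 4. Code and letter together were read as naming the cell line within a genotype, and 6 lines appear in both states. Deviations from group means correlated across genes at 0.0207 to 0.163 (median 0.0972) for the 6 same-line pairs, against -0.110 to 0.0751 for 18 pairs of other lines of the same genotype. The pairing of transformation comparisons by line comes from these labels, and the fit with line as a block is given beside a result where it changed a call or moved a count by over 1.5 times. The code was also treated as a possible batch, with counts recomputed within each code. Other alternatives were RLE, upper quartile and library size scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, only the groups compared, a fold minimum, a stricter threshold, a block on replicate number, sequencing runs as a covariate, leaving out X and Y genes, and leaving out each library in turn. After the data had been seen, a fit without both WT untransformed replicate 3 and the library labelled KO p210 replicate 2 was added.

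Each test was checked on simulated counts with 200 changed genes. For KO against WT in untransformed lines, edgeR recovered 20.9% of genes changed 1.5-fold, 47.8% at 2-fold and 74.2% at 4-fold, with 3 false calls among 14190 simulated genes tested, where DESeq2 made 162 calls, 38 of them false. Recovery of 2-fold changes in the simulated interaction was 31.3%. The simulated counts were drawn with the dispersions that edgeR estimated here. They held no differences in spread between groups and no effect of line or code. They therefore do not give the share of false calls of either tool in the real data. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom between replicates was at least 15.3.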

Results

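Expression was measured by RNA sequencing in 14 HPC-LSK cultures that differed in Cdk6 genotype and in transformation by BCR-ABL p210, with 4 WT untransformed, 3 KO untransformed, 3 WT p210 and 4 KO p210 libraries. Total counts ranged from 20270348 to 50303271 per library, with 18105 to 20689 genes detected and 1.48% to 2.13% of counts from mitochondrial genes. The comparisons ask which transcripts differ between Cdk6-deficient and wild-type progenitors before and after transformation, and which differ between transformed and untransformed lines. By the protocols p210 cells were grown without IL-6 and SCF, so each change given below with p210 also holds the change of medium.

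Cdk6 (chromosome 5, 3341485 to 3531008, GRCm38, ENSMUSG00000040274.11), the cyclin D-dependent kinase removed in the knockout, stood at 1122 ± 163 CPM in WT untransformed libraries (SD, n = 4) and 255 ± 17.6 CPM in KO untransformed libraries (n = 3). The log2 fold change was -2.14 ± 0.34 (SE, adjusted p = 0.00573). It was past the threshold in each alternative except that with the libraries of the second code alone (replicates 3 and 4 of each group), where the log2 fold change was -2.45 (adjusted p = 0.236). In p210 lines Cdk6 was at 593 ± 15.6 CPM in WT (n = 3) and 328 ± 179 CPM in KO (n = 4), a log2 fold change of -0.86 ± 0.31 that did not pass the test (adjusted p = 0.147). The library labelled KO p210 replicate 2 held 578 CPM, inside the range of 576 to 606 CPM of the WT p210 libraries, while the other KO p210 libraries held 163 to 326 CPM. Without it the log2 fold change was -1.28 (adjusted p = 0.0143). The Cdk6 level of this library goes against its label, and every direction given below for KO p210 includes it unless stated. The labels do not say which exons the knockout allele lacks, so remaining reads need not come from a functional transcript.

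Bcr (chromosome 10, 75060592 to 75184921) and Abl1 (chromosome 2, 31688376 to 31804227), the mouse genes whose human counterparts are fused in BCR-ABL, rose with p210 in both genotypes. Bcr went from 70.4 ± 4.54 to 237 ± 69.7 CPM in WT (log2 fold change 1.75 ± 0.15, adjusted p = 1.66e-05) and from 70.9 ± 2.54 to 302 ± 30.1 CPM in KO (2.09 ± 0.17, adjusted p = 1.12e-05). Abl1 went from 224 ± 10.9 to 474 ± 117 CPM in WT (1.08 ± 0.13, adjusted p = 9.87e-05) and from 222 ± 14.6 to 534 ± 33.5 CPM in KO (1.27 ± 0.14, adjusted p = 6.13e-05). The counts do not separate reads of an introduced fusion from reads of the mouse genes.

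**Figure D1:**
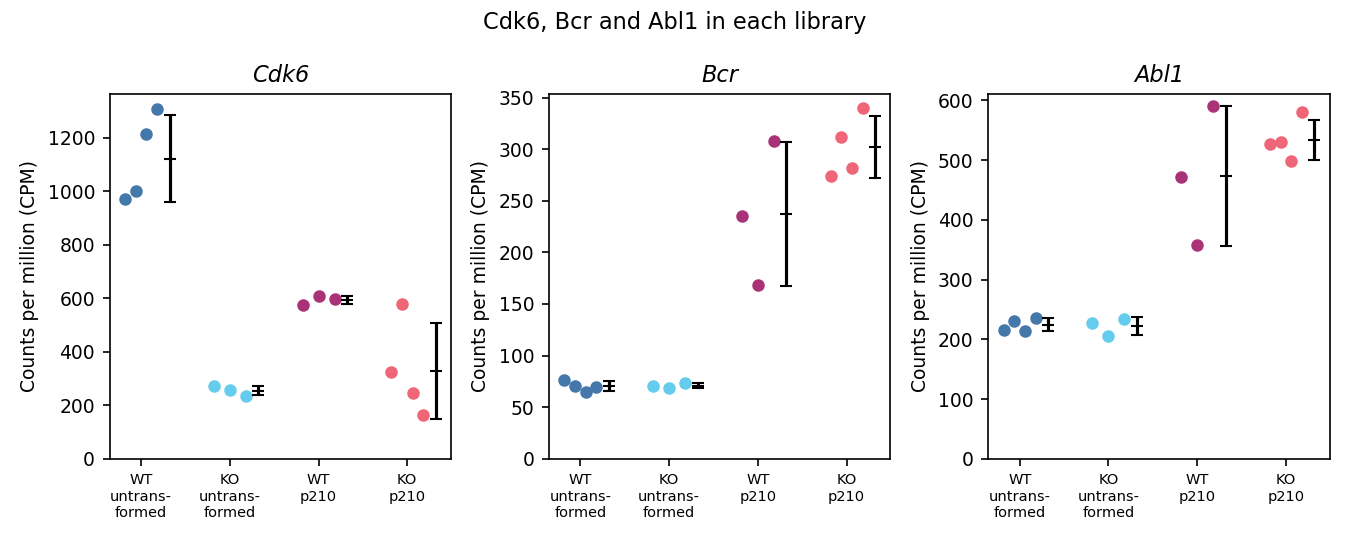
CPM (vertical axis, linear, from 0) of Cdk6, Bcr and Abl1 in each of the 14 libraries, by group; each point is 1 library and the bar beside the points gives the mean and SD of the group. The library labelled KO p210 replicate 2 holds 578 CPM of Cdk6, among the WT p210 libraries at 576 to 606, and Bcr and Abl1 stand higher in every p210 library than in every untransformed one.

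Over the 500 most variable genes, the first principal component held 62.1% of the variance and parted p210 from untransformed libraries. It also parted the genotypes within each state. KO libraries lay at -41 to -36.1 against -58.2 to -50.9 for WT in untransformed libraries. In p210 libraries KO lay at 53.4 to 66.9 against 16.4 to 45.7 for WT. The second held 12.4%, and on it KO libraries lay below WT libraries of the same state, at -23.9 to -18.9 against -4.4 to 23.3 in untransformed and -25.7 to -1.4 against 29.4 to 39.3 in p210 libraries. WT untransformed replicate 3 stood apart from its group on the third component (6.56% of the variance), at -40.1 against -9.1 to 4.9 for the other WT untransformed libraries.

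**Figure D2:**
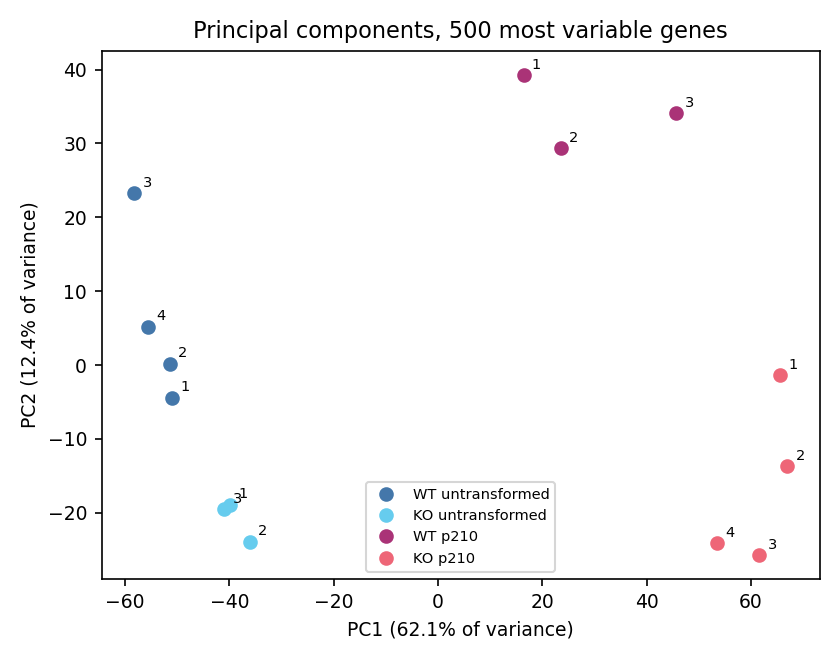
First and second principal components (percent of variance on each axis) of log2 CPM over 500 genes, 1 point per library, labelled by replicate number. Untransformed libraries lie at negative values of the first component and p210 libraries at positive values.

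In untransformed lines, 20 of 30 DNA replication, 12 of 28 mitosis, 7 of 19 megakaryocyte and 3 of 14 erythroid genes were lower in KO than in WT cells, and 8 of 35 neutrophil and monocyte, 9 of 38 adhesion and 6 of 24 receptor genes were higher. Camera called each of these lists, and each call was lost with an estimated correlation (adjusted p = 0.222 to adjusted p = 0.49 with an estimated correlation). Of 14512 genes tested, 2211 passed the test, 1267 higher and 944 lower in KO than in WT. Of 30 DNA replication and E2F target genes, 20 fell (23 adjusted over the list alone), among them Lig1, which seals nicks in replicated DNA (log2 fold change -0.77 ± 0.10, adjusted p = 0.00271), Pole (-0.55 ± 0.07) and the helicase subunit Mcm4 (-0.63 ± 0.09). The list was called down by camera (adjusted p = 3.64e-15; adjusted p = 0.222 with an estimated correlation). Of 28 mitosis genes, 12 fell (21 adjusted over the list alone), including Top2a (-0.42 ± 0.07) and Nusap1 (-0.72 ± 0.13). The mitosis list had a camera adjusted p of 4.05e-10 (adjusted p = 0.357 with an estimated correlation). Among G1 regulators, 4 of 19 fell and 1 rose (5 and 3 adjusted over the list alone). Rbl1, a pocket protein, fell (-0.48 ± 0.07), as did the CDK inhibitor gene Cdkn2c (-1.46 ± 0.22, from 37.6 ± 6.3 to 13.7 ± 1.8 CPM), while Cdkn1c rose (3.30 ± 0.87, adjusted p = 0.0287).

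Lineage genes moved in both directions in the untransformed KO lines. Of 35 neutrophil and monocyte genes, 8 rose (13 adjusted over the list alone), among them the transcription factor gene Spi1 (1.20 ± 0.21, adjusted p = 0.00735) and the lysozyme genes Lyz1 (3.38 ± 0.75) and Lyz2, which went from 1192 ± 871 to 9015 ± 2333 CPM. Camera called the list up (adjusted p = 3.96e-10; adjusted p = 0.357 with an estimated correlation). Mpo, myeloperoxidase, averaged 2605 CPM in WT and 13005 CPM in KO and did not pass (adjusted p = 0.218). Of 38 adhesion and homing genes, 9 rose (13 adjusted over the list alone), including the chemokine receptor gene Ccr1 (2.24 ± 0.43), Vav1 (0.51 ± 0.11) and the integrin gene Itgb2 (1.15 ± 0.24). Camera tested the adhesion list at adjusted p = 0.00208 (adjusted p = 0.332 with an estimated correlation). Of 24 cytokine and growth factor receptor genes, 6 rose (8 adjusted over the list alone, beside 3 that fell), including Il6ra (1.66 ± 0.26), Ifnar1 (0.84 ± 0.14) and Csf2rb (1.42 ± 0.27). The receptor genes as a list had camera adjusted p = 0.00037 (adjusted p = 0.222 with an estimated correlation). Of 31 interferon response genes, 5 rose (7 adjusted over the list alone), with Stat2 at 0.80 ± 0.17 and Xaf1 at 2.12 ± 0.45 and camera adjusted p = 0.00332 (adjusted p = 0.551 with an estimated correlation). Of 19 megakaryocyte genes, 7 fell (10 adjusted over the list alone), including Itga2b (-1.68 ± 0.34) and Vwf (-2.24 ± 0.59). The megakaryocyte list had a camera adjusted p of 0.00037 (adjusted p = 0.49 with an estimated correlation). Of 14 erythroid genes, 3 fell (6 adjusted over the list alone), including Zfpm1 (-1.47 ± 0.31) and the carbonic anhydrase gene Car2 (-3.21 ± 0.94). Camera tested the erythroid list at adjusted p = 0.00203 (adjusted p = 0.357 with an estimated correlation). Of 32 stem and multipotent progenitor markers, 2 fell and 1 rose (2 fell adjusted over the list alone); Gata2 (-0.85 ± 0.20) and Angpt1 (-0.84 ± 0.22) fell. The stem and progenitor genes as a list had camera adjusted p = 0.00192 (adjusted p = 0.332 with an estimated correlation).

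By the rule for single genes, the largest rises in untransformed KO lines were those of Eno1b (0.0680 CPM in WT and 11.5 ± 4.6 CPM in KO, adjusted p = 0.00764), Pla2r1 (6.48 ± 0.93), Myh15 (4.32 ± 1.05), Nlrp1b (4.22 ± 0.77) and Lrmda (chromosome 14, 22019712 to 23056085), which went from 1.30 ± 0.21 to 24.0 ± 1.5 CPM (4.21 ± 0.19, adjusted p = 3.37e-07). Eno1b is a near copy of Eno1 and its counts are uncertain. Among the largest falls were those of Dlk1 (-5.24 ± 1.20), Ank3 (-3.93 ± 0.86) and the secreted Wnt antagonist gene Sfrp2 (-3.90 ± 0.59, from 25.3 ± 7.2 to 1.68 ± 0.97 CPM). In 5758 genes (39.7%) the libraries of the genotypes did not overlap, against 5.71% by chance.

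The count of 2211 depended on single libraries. It was 181 without KO untransformed replicate 2, 691 without KO untransformed replicate 1, 928 without WT untransformed replicate 4, 1195 without WT untransformed replicate 3, and 920 without both WT untransformed replicate 3 and the library labelled KO p210 replicate 2. Of the 36 named genes that passed here, 22 lost their call without KO untransformed replicate 2 (adjusted p 0.0516 to 0.163); Cdk6, Eno1b, Pla2r1, Nlrp1b, Lrmda, Sfrp2, Lig1, Pole, Mcm4, Top2a, Rbl1, Cdkn2c, Il6ra and Ifnar1 kept it. Over all 29 alternatives Car2 lost its call in 13, Cdkn1c in 11, Angpt1 and Vwf in 10, Myh15 in 9 and Dlk1 in 7 (adjusted p up to 0.336). Without KO untransformed replicate 1, 9 of the 36 lost their call (adjusted p up to 0.129), without WT untransformed replicate 4, 8 did (up to 0.0822), without KO untransformed replicate 3, 5 did (up to 0.152), without WT untransformed replicate 3, 4 did (up to 0.0712), without WT untransformed replicate 2, 2 did (up to 0.0519) and without the library labelled KO p210 replicate 2, 1 did (0.0532). With the first code alone (2 against 2 libraries) 435 genes passed and 16 of the 36 named genes lost their call (adjusted p up to 0.336), and with the second code alone (1 against 2) edgeR called 0, with 2466 at an unadjusted p under 0.05. With limma-voom 5 of the 36 named genes lost their call (adjusted p 0.0731 to 0.136). Upper quartile scaling gave 1077 higher and 1362 lower, and library size scaling 915 higher and 1657 lower. Library size scaling moved the median of all genes by -0.10.

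In p210 lines, 9 of 32 stem and progenitor, 9 of 30 DNA replication, 5 of 14 erythroid, 4 of 31 interferon response and 2 of 19 megakaryocyte genes were lower in KO than in WT cells. Camera called each of these lists down, and each call was lost with an estimated correlation (adjusted p = 0.116 to adjusted p = 0.529 with an estimated correlation). Of 14512 genes tested, 645 passed, 128 higher and 517 lower in KO than in WT. Of 32 stem and multipotent progenitor markers, 9 fell (15 adjusted over the list alone), among them the transcription factor genes Hlf (22.1 ± 25 CPM in WT, 0.190 ± 0.085 CPM in KO, adjusted p = 0.00323) and Mecom (-7.67 ± 1.30) and the surface receptor gene Slamf1 (-5.15 ± 0.83). The camera test gave adjusted p = 1.48e-08 (adjusted p = 0.116 with an estimated correlation). Of 14 erythroid genes, 5 fell (8 adjusted over the list alone), including Gata1 (-4.41 ± 0.82). Camera gave adjusted p = 6.57e-06 (adjusted p = 0.411 with an estimated correlation). Of 19 megakaryocyte genes, 2 fell (7 adjusted over the list alone), namely the platelet glycoprotein genes Gp1ba (-3.63 ± 0.69) and Gp9 (-4.09 ± 0.90). The megakaryocyte list had a camera adjusted p of 0.000132 (adjusted p = 0.529 with an estimated correlation), and within the second code its direction was up (0.977). Of 30 DNA replication genes, 9 fell (12 adjusted over the list alone), including Lig1 (-0.67 ± 0.09) and Pola1 (-0.47 ± 0.09). Camera tested the DNA replication list at adjusted p = 6.26e-07 (adjusted p = 0.481 with an estimated correlation). Cdkn2c (-1.38 ± 0.21) and Rbl1 (-0.41 ± 0.07) fell.

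Mitosis genes had a median log2 fold change of -0.02 in this comparison, while camera gave the direction as up (adjusted p = 0.874). Of 31 interferon response genes, 4 fell in KO p210 (5 adjusted over the list alone), including Oasl2 (1.84 ± 0.70 CPM in WT, 0.0770 ± 0.053 CPM in KO) and Usp18 (-2.05 ± 0.36). The interferon genes as a list had camera adjusted p = 2.09e-05 (adjusted p = 0.481 with an estimated correlation). Among receptor genes 3 of 24 fell (4 adjusted over the list alone, beside 1 that rose), including Il6st (-3.37 ± 0.80). The list's median (0.14) and mean (-0.42) differed in sign and camera gave adjusted p = 0.999. In the integrated stress and amino acid response list, 2 of 22 rose, the folate enzyme gene Mthfd2 (0.78 ± 0.18) and the serine synthesis gene Phgdh (0.53 ± 0.13), and 1 fell (3 and 1 adjusted over the list alone). The camera test gave adjusted p = 0.00326 (adjusted p = 0.481 with an estimated correlation), which was 0.159 without WT p210 replicate 3 and 0.0539 without KO p210 replicate 3. The adhesion gene Selplg rose (0.99 ± 0.25, adjusted p = 0.043), as did Nfkbia (1.68 ± 0.37). Camera called the neutrophil and monocyte list up (adjusted p = 0.00149; adjusted p = 0.871 with an estimated correlation; 0.0738 without KO p210 replicate 4). In edgeR 0 of its 35 genes passed, also adjusted over the list alone, with 7 at an unadjusted p under 0.05; DESeq2 called 2 and limma-voom 0. Lyz2 averaged 2249 CPM in WT and 6088 CPM in KO (adjusted p = 0.271), and Mpo had an adjusted p of 0.319.

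By the same rule, the largest rises in KO p210 were those of Gsta3 (3.74 ± 0.92), Lrmda (3.43 ± 0.21, adjusted p = 7.7e-06), Ubash3a (3.33 ± 0.77) and AA465934 (2.68 ± 0.34). Among the largest falls, Megf10 had 544 counts in WT and none in KO, so it was at least 205-fold lower against a floor of 3 counts over the KO group. Mest had 1359 counts in WT against 2 (ratio 878, 95% interval 243 to 7255), Ccl8 783 against 1 (ratio 1011, 181 to 40001) and Arhgef5 (chromosome 6, 43265582 to 43289320), 938 against 2 (ratio 606, 167 to 5010). Pdcd1, the PD-1 receptor gene, stood at 115 CPM in WT and 0.110 CPM in KO (adjusted p = 0.00155). WT p210 libraries differed among themselves in these genes, with SDs of 8.8 CPM around a mean of 5.85 CPM for Megf10 and 160 CPM around 115 CPM for Pdcd1.

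The count of 645 depended on the libraries in the fit. When only the 7 p210 libraries were fitted, edgeR called 5 genes (1793 at an unadjusted p under 0.05), and of 25 named genes tested there only Lrmda and Arhgef5 kept their call. With limma-voom on all libraries 386 genes passed, and 17 of the 29 named genes that passed in edgeR lost their call, among them Hlf, Mecom, Slamf1, Gata1, Gp1ba, Gp9, Oasl2, Ccl8, Megf10 and Pdcd1 (adjusted p 0.0798 to 0.293). Il6st and Phgdh lost their call in 19 of 29 alternatives, Gsta3 and Selplg in 17, Nfkbia and Ubash3a in 10, and Gp9 and Mthfd2 in 9 (adjusted p up to 0.740). The count was 285 without WT p210 replicate 1, 305 without the library labelled KO p210 replicate 2 and 275 without both WT untransformed replicate 3 and the library labelled KO p210 replicate 2. Of the 29 named genes that passed, 12 lost their call without WT p210 replicate 1 (adjusted p up to 0.160), 9 without the library labelled KO p210 replicate 2 (up to 0.0930), 7 without KO p210 replicate 3 (up to 0.0832) and 6 without WT p210 replicate 3 (up to 0.0983). At most 5 lost it without any other single library (up to 0.0959); these were WT p210 replicate 2, KO p210 replicates 1 and 4, KO untransformed replicates 1, 2 and 3, and WT untransformed replicates 1, 2 and 4. Within the first code (2 against 2 libraries) 655 genes passed and within the second code (2 against 1) 4 did, where 27 of the 29 named genes lost their call (adjusted p up to 0.740). Library size scaling gave 69 higher and 722 lower. In 1935 genes (13.3%) the libraries of the genotypes did not overlap, against 5.71% by chance.

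The genotype effects in the 2 states share no library, though they share lines if code and letter name the line. Across 14512 genes, which are not independent replicates, their log2 fold changes correlated at r = 0.459 (Spearman correlation 0.445). Of the genes called, 70 were higher in KO in both states, among them Lrmda, against 11.2 for independent lists, and 147 were lower in both, including Lig1, Rbl1 and Cdkn2c, against 33.6. Both comparisons come from the same fit and use the same estimate of spread for each gene, which can raise the overlap of calls. The values for independent lists are thus a scale and not a test.

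In WT lines, 14 of 24 p53 targets and 11 of 21 STAT5 targets were higher with p210, and 23 of 30 DNA replication, 8 of 14 erythroid, 11 of 32 stem and progenitor and 7 of 19 megakaryocyte genes were lower. Against these directions, 4 STAT5 targets fell and 1 erythroid and 2 stem and progenitor genes rose. Camera called each of these lists, and each call was lost with an estimated correlation (adjusted p = 0.0682 to adjusted p = 0.609 with an estimated correlation). Of 14512 genes, 5727 passed (39.5%), 3173 higher and 2554 lower in p210. Of 21 STAT5 targets, 11 rose and 4 fell (12 and 4 adjusted over the list alone), with the feedback inhibitor genes Socs2 going from 3.96 ± 1.6 to 153 ± 20 CPM (5.26 ± 0.29, adjusted p = 1.05e-06) and Cish from 10.5 ± 2.4 to 183 ± 26 CPM (4.12 ± 0.39), and with Lif at 5.24 ± 0.59. Camera gave adjusted p = 0.00152 (adjusted p = 0.258 with an estimated correlation). Of 24 p53 targets, 14 rose (15 adjusted over the list alone), among them Sesn2 (1.54 ± 0.12), Ccng1 (1.27 ± 0.13) and Polk (1.33 ± 0.14). The p53 target list had a camera adjusted p of 4.19e-08 (adjusted p = 0.0682 with an estimated correlation). Of 22 apoptosis regulators, 13 rose and 3 fell (the same numbers adjusted over the list alone), including the death effector genes Bax (1.03 ± 0.11) and Bak1 (0.48 ± 0.07). Camera tested the apoptosis list at adjusted p = 0.0121 (adjusted p = 0.357 with an estimated correlation). Of 30 DNA replication genes, 23 fell (24 adjusted over the list alone), including Pola1 (-1.21 ± 0.09) and Lig1 (-1.06 ± 0.10). The DNA replication genes as a list had camera adjusted p = 7.49e-14 (adjusted p = 0.258 with an estimated correlation). Of 28 mitosis genes, 11 fell and 1 rose (13 and 2 adjusted over the list alone), with Top2a at -0.47 ± 0.07 and camera adjusted p = 0.00349 (adjusted p = 0.691 with an estimated correlation; 0.0501 without WT p210 replicate 3).

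The CDK inhibitor genes Cdkn2b (5.33 ± 0.49) and Cdkn2a (5.06 ± 0.69, from 2.08 ± 1.4 to 68.9 ± 17 CPM) rose in WT p210, as did the D-type cyclin gene Ccnd2 (1.11 ± 0.15). In total 6 of 19 G1 regulators rose and 3 fell, as they did adjusted over the list alone, and camera gave adjusted p = 0.415. Of 32 stem and progenitor markers, 11 fell and 2 rose (12 and 2 adjusted over the list alone). The SCF receptor gene Kit fell from 431 ± 51 to 45.5 ± 12 CPM (-3.25 ± 0.31), and Etv6 fell by 0.73 ± 0.07 on the log2 scale. The camera test gave adjusted p = 0.000741 (adjusted p = 0.258 with an estimated correlation). Of 14 erythroid genes, 8 fell and 1 rose (as adjusted over the list alone), with Zfpm1 at -2.03 ± 0.32 and Icam4 at -2.11 ± 0.40 and camera adjusted p = 0.00416 (adjusted p = 0.373 with an estimated correlation). Of 19 megakaryocyte genes, 7 fell (11 adjusted over the list alone), with Selp at -7.09 ± 0.74 and Treml1 at -5.09 ± 0.90. Camera gave adjusted p = 0.00513 (adjusted p = 0.609 with an estimated correlation; 0.0637 with line as a block). Of 18 mast cell and basophil genes, 8 rose and 4 fell, as they did adjusted over the list alone, with the basophil protease gene Mcpt8 going from 51.7 ± 48 to 3409 ± 2797 CPM (6.05 ± 0.80) and Alox15 rising by 6.62 ± 0.88 on the log2 scale. The list's median (1.53) and mean (-0.18) differed in sign, and camera gave adjusted p = 0.0731. Of 38 adhesion genes, 15 rose and 3 fell (16 and 3 adjusted over the list alone), including Itgav (0.92 ± 0.09) and Ccr1 (3.65 ± 0.45). The camera test gave adjusted p = 0.0453 (adjusted p = 0.557 with an estimated correlation; 0.0715 with line as a block). This call was lost in 10 of the 14 removals of a single library, all but WT untransformed replicates 1, 2 and 3 and WT p210 replicate 1, with adjusted p up to 0.136. Of 31 interferon genes, 6 rose, among them Stat2 (1.05 ± 0.17) and Mx1 (4.23 ± 0.75), and 6 fell, among them Oasl2 (-2.48 ± 0.53), as they did adjusted over the list alone (camera adjusted p = 0.467). Cdk6 itself fell in WT p210 (-0.92 ± 0.32, adjusted p = 0.0386), a call lost in several alternatives. Among them were line as a block (adjusted p = 0.0921) and the removal of each of WT untransformed replicates 3 and 4 and WT p210 replicates 1, 2 and 3 (adjusted p up to 0.0868).

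Some of the largest changes in WT p210 were of genes with almost no reads in 1 of the states. Tcrg-C1, a T cell receptor constant gene, had 8317 counts in WT p210 against 3 in WT untransformed (ratio 5165, 95% interval 1767 to 25053), and Emx2 3980 against 3 (ratio 2472, 845 to 11991). Lef1 was at least 446-fold higher against a floor of 3 counts over the untransformed group, and Crisp1 rose by 10.99 ± 1.82 on the log2 scale. In the other direction, the imprinted noncoding gene Rian was at least 600.4-fold and Fam181b at least 156-fold lower against the same kind of floor, Arhgap32 had 6882 counts against 1 (ratio 3694, 663 to 145913) and Dock1 1829 against 1 (ratio 982, 176 to 38794). Emx2 lost its call with limma-voom (adjusted p = 0.293) and within each code (0.0591 and 0.0742), Crisp1 with limma-voom (0.0714), and Dock1 (0.0787) and Lef1 (0.0520) within the second code. Rian lost its call in 10 of 29 alternatives (up to 0.224), among them those without WT untransformed replicate 2, 3 or 4 or WT p210 replicate 1, 2 or 3 (up to 0.0784). In 6533 genes (45.0%) the groups did not overlap, against 5.71% by chance. Within the first code (2 against 2) 3725 genes passed and within the second code (1 against 2) 1566, where 11 of 39 named genes lost their call (adjusted p up to 0.320). Upper quartile scaling gave 2709 higher and 3265 lower, and library size scaling 2516 higher and 3471 lower, the latter with a shift of the median of all genes by -0.12.

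In KO lines, 16 of 24 p53 targets and 12 of 21 STAT5 targets were higher with p210, and 21 of 30 DNA replication, 18 of 32 stem and progenitor, 17 of 31 interferon response, 8 of 14 erythroid and 9 of 19 megakaryocyte genes were lower. In the other direction, 3 STAT5 targets fell, and 1 interferon response, 2 stem and progenitor and 2 megakaryocyte genes rose. Camera called each of these lists, and each call was lost with an estimated correlation (adjusted p = 0.0528 to adjusted p = 0.612 with an estimated correlation). Of 14512 genes, 5395 passed (37.2%), 2790 higher and 2605 lower in p210. With line as a block, which pairs 3 lines, 3586 passed. Of 21 STAT5 targets, 12 rose and 3 fell, as they did adjusted over the list alone; Socs2 (4.52 ± 0.31) and Cish (4.33 ± 0.43) rose and Socs3 fell (-1.89 ± 0.20). The STAT5 list had a camera adjusted p of 0.00239 (adjusted p = 0.253 with an estimated correlation). Of 24 p53 targets, 16 rose (16 adjusted over the list alone), including the kinase gene Plk3 (2.69 ± 0.23), Sesn2 (1.38 ± 0.12) and Ccng1 (1.29 ± 0.13). Camera tested the p53 target list at adjusted p = 4.84e-09 (adjusted p = 0.0528 with an estimated correlation). Bax rose (0.89 ± 0.11), as 10 of 22 apoptosis regulators did while 3 fell, also adjusted over the list alone (camera adjusted p = 0.0624; 0.0268 with line as a block; adjusted p = 0.386 with an estimated correlation and no block). Of 30 DNA replication genes, 21 fell (23 adjusted over the list alone), with Pola1 at -1.02 ± 0.09 and Lig1 at -0.96 ± 0.09 and camera adjusted p = 3.49e-07 (adjusted p = 0.257 with an estimated correlation). Of 28 mitosis genes, 6 rose and 2 fell, as they did adjusted over the list alone, with Aurka at 0.61 ± 0.14 and Plk1 at 0.53 ± 0.13. Plk1 lost its call with line as a block (adjusted p = 0.0966), and camera gave adjusted p = 0.226 for the list. Cdkn2b (4.08 ± 0.51) and Cdkn2a (6.25 ± 0.83) rose.

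Of 31 interferon response genes, 17 fell and 1 rose in KO p210 against KO untransformed, as they did adjusted over the list alone. Oasl2 went from 10.7 ± 4.3 to 0.0770 ± 0.053 CPM, Rtp4 from 7.74 ± 2.4 to 0.0770 ± 0.053 CPM and the guanylate-binding protein gene Gbp3 from 10.4 ± 2.2 to 1.94 ± 1.0 CPM. Camera gave adjusted p = 3.49e-07 (adjusted p = 0.257 with an estimated correlation). Of 32 stem and progenitor markers, 18 fell and 2 rose, also adjusted over the list alone, with Kit at -3.04 ± 0.29 and Etv6 at -0.65 ± 0.07 and camera adjusted p = 1.05e-06 (adjusted p = 0.175 with an estimated correlation). Of 14 erythroid genes, 8 fell (9 adjusted over the list alone); the aquaporin gene Aqp1 had 346 counts in KO untransformed against 1 in KO p210 (ratio 369, 95% interval 65.9 to 14630). The erythroid genes as a list had camera adjusted p = 0.000387 (adjusted p = 0.257 with an estimated correlation). Of 19 megakaryocyte genes, 9 fell and 2 rose (10 and 2 adjusted over the list alone), with Selp at -7.15 ± 0.68 and Gp1ba at -3.86 ± 0.69 and camera adjusted p = 0.00742 (adjusted p = 0.612 with an estimated correlation). Of 18 mast cell and basophil genes, 6 rose (6 adjusted over the list alone, beside 2 that fell), including Cd200r3 (4.14 ± 0.74) and Il13, with 289 counts against 2 (ratio 135, 37.1 to 1123), and camera gave adjusted p = 0.344. Cdk6 did not pass (0.36 ± 0.32, adjusted p = 0.394).

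Among genes named by the rule with reads in both states, Ccn3 rose most in KO p210 (11.19 ± 1.69). The stefin genes Stfa1 and Stfa2, near copies whose reads may be shared, were at least 362-fold and 261-fold higher, and Lce6a at least 185-fold higher, each against a floor of 3 counts over the KO untransformed group. Pla2r1 was at least 154-fold lower against the floor of the KO p210 group, Kcnk12 had 799 counts against 1 (ratio 853, 153 to 33731), and the creatine synthesis gene Gatm fell (-9.47 ± 1.82). With limma-voom 5 of the 34 named genes that passed lost their call (adjusted p 0.0538 to 0.126). In 6697 genes (46.1%) the groups did not overlap, against 5.71% by chance. Within the first code (2 against 2) 4186 genes passed and within the second code (2 against 1) 73 did, where 31 of 34 named genes lost their call (adjusted p up to 0.289). Library size scaling gave 2093 higher and 3466 lower, with a shift of the median of all genes by -0.11.

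**Figure D3:**
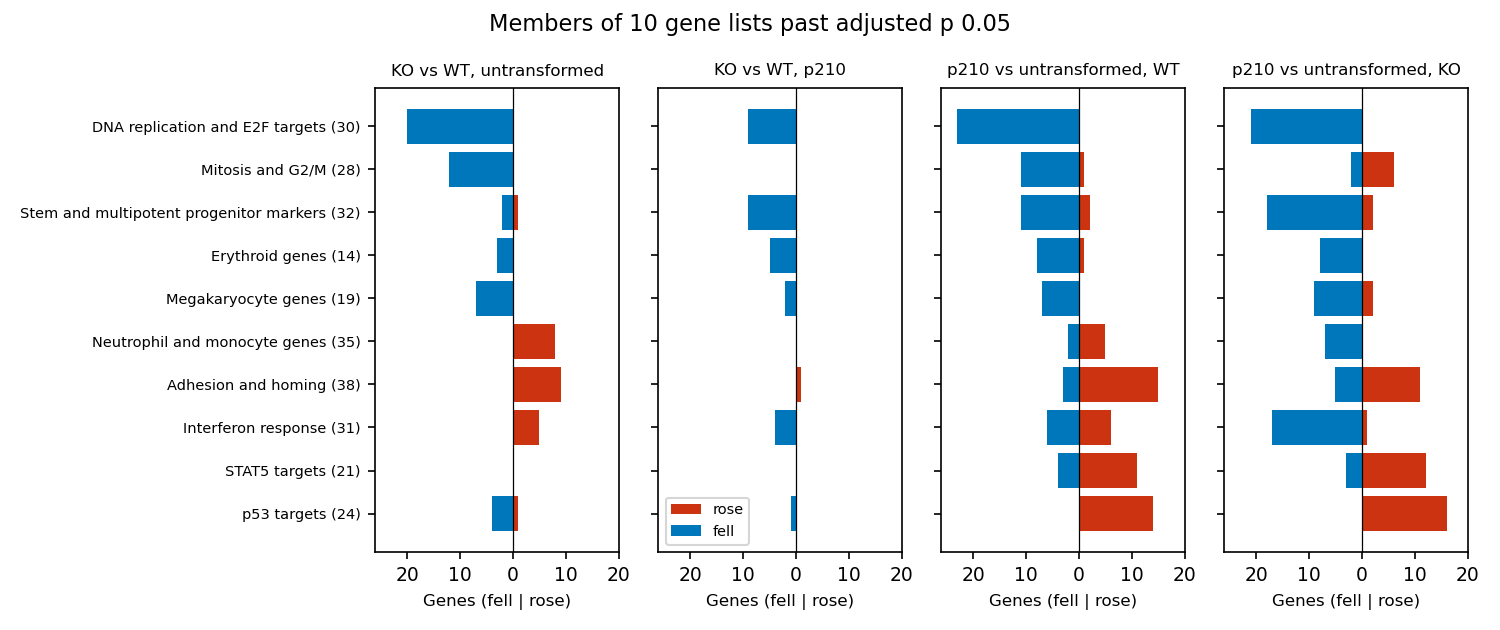
Numbers of members of 10 gene lists that rose (right of 0) or fell (left of 0) past an adjusted p of 0.05 in edgeR's quasi-likelihood test, in 4 comparisons; tested members are in parentheses. DNA replication genes fell in all 4 comparisons (20, 9, 23 and 21 of 30), and p53 targets rose with p210 in WT (14 of 24) and KO (16 of 24).

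The transformation effects of the genotypes share no library and no line. Both do share the change of medium, since by the protocols p210 cells were grown without IL-6 and SCF. Genes that moved in both genotypes may thus follow p210 or the medium, which cannot be separated. Their log2 fold changes correlated across genes at r = 0.748 (Spearman correlation 0.711). Of the genes called, 2042 rose with p210 in both, such as Socs2, Cish, Sesn2, Ccng1 and Bax, against 610 for independent lists, and 1571 fell in both, such as Kit, Pola1 and Lig1, against 458. Here too the same fit and estimate of spread serve both comparisons, so these values for independent lists are no test.

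The interaction asks whether the KO effect differed between p210 and untransformed lines. It passed for 5 genes, each with a lower KO effect in p210. They were Arhgef5 (-7.33 ± 0.88, adjusted p = 0.0306; with 2 counts in KO p210 this fitted value depends on the prior count), Tceal8 (chromosome X, 136168984 to 136172342; -7.01 ± 0.89, adjusted p = 0.0306), the amino acid transporter gene Slc43a1 (-4.41 ± 0.58, adjusted p = 0.0306), Nxpe5 (-2.08 ± 0.30, adjusted p = 0.0408) and the interferon-induced gene Ifitm2 (-0.76 ± 0.11, adjusted p = 0.0408). Tceal8 stood at 26.7 ± 7.3, 17.0 ± 8.4, 8.57 ± 0.75 and 0.0390 ± 0.078 CPM in WT untransformed, KO untransformed, WT p210 and KO p210, and Nxpe5 at 45.4 ± 8.0, 155 ± 10, 32.2 ± 11 and 26.0 ± 4.7 CPM. Only KO p210 replicate 4 of its group had counts of Tceal8, so the size of its fitted value is also uncertain. Cdk6 did not pass (1.28 ± 0.45, adjusted p = 0.272). Of 31 interferon response genes, 12 were lower adjusted over the list alone. The interferon list had a camera adjusted p of 1.81e-13 (adjusted p = 0.205 with an estimated correlation). The mitosis list was higher (4 of 28 adjusted over the list alone, camera adjusted p = 9.86e-13; adjusted p = 0.423 with an estimated correlation), and the receptor list lower (camera adjusted p = 6.38e-05; adjusted p = 0.205 with an estimated correlation).

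The gene calls of the interaction did not outlast most changes of the fit. With line as a block edgeR called 0 genes (1142 at an unadjusted p under 0.05), where DESeq2 without the block called 409 and limma-voom 4. Within the first code the count was 32, and within the second code edgeR called 0 (1617 at an unadjusted p under 0.05). The count was 0 without WT untransformed replicate 2 or 4, KO untransformed replicate 1 or 3, or the library labelled KO p210 replicate 2 (1567 to 2063 at an unadjusted p under 0.05), 1 without WT untransformed replicate 3 or KO untransformed replicate 2, and 2 without KO p210 replicate 3. It was 8 without WT untransformed replicate 1, 13 without KO p210 replicate 1, 26 without WT p210 replicate 2, 43 without KO p210 replicate 4 and 46 without WT p210 replicate 3.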

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

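The tests of a mislabelled or mixed library, of copies around Cdk6, of donor sequence, of pseudogenes and of scaling, and the counts over other splits of the samples, were chosen only after the results they bear on had been seen. Those of depth and of a single WT p210 library were written down first.

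The library labelled KO p210 replicate 2 held 578 CPM of Cdk6, against 244 ± 81.5 CPM in the other KO p210 libraries (SD, n = 3). A WT sample under the wrong label does not match the tables, since 100% of the 9 genes that parted the other 6 KO from the 7 WT libraries at least 2-fold placed it with KO. WT p210 cells mixed into it would need a share of 95.5%, while 6 genes abundant in WT p210 and nearly absent from the other KO p210 libraries stood at a median of 0.185% of the WT p210 mean (highest 10.8%). Extra copies of the region do not match either, with a median log2 ratio of 0.00191 over 20 genes within 5 Mb (bootstrap 95% interval -0.17 to 0.12), against 1.30 for Cdk6. KO untransformed replicate 2, the same line by code and letter, held 258 CPM of Cdk6, within the 236 to 271 CPM of the KO untransformed libraries. Copies of Cdk6 alone and more transcript from the targeted allele in this p210 culture may remain as candidate explanations, and no biological explanation was tested.

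Of the 217 genes called in the same direction for genotype in both states, 0% lay within 20 Mb of Cdk6, where 0.441% of tested genes lie (64 genes, Fisher's exact p = 1). None of the 217 was thus a gene of that window. With 64 tested genes the window could supply only a minority of the 217, so this count cannot decide on donor sequence around the targeted locus. Annotated pseudogenes made up 2.76% of the 217, against 4.44% of tested genes (Fisher's exact p = 0.316). Among the 5 genes parted at least 4-fold between all KO and all WT libraries, named after their values were seen (Lrmda, Eif5al3-ps, Gm6969, Gm26510 and Gm26637), 40% were annotated pseudogenes, and with 5 genes read sharing cannot be told apart from a change of the gene itself; an earlier version of this test that also counted genes with predicted-gene names gave 80% (4 of 5), against 10.4% of tested genes (Fisher's exact p = 0.000542), and was narrowed after that value was seen. Lrmda, a protein-coding gene, stood at 20.1 CPM in KO and 1.43 CPM in WT libraries. A difference between the founder lines that is unlinked to Cdk6 could underlie such genes and was not tested, nor was loss of Cdk6 itself.

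In KO p210 against WT p210, 517 genes were lower and 128 higher. With other scalings the highest share of higher genes among the calls was 18.8%, against 19.8% with TMM. Each of these scalings moved the median of all genes down, by -0.0076 to -0.0959 on the log2 scale. They could thus only lower this share and do not decide whether scaling accounts for the balance. With all libraries thinned to 20270348 counts the share was 20.2% (114 of 564), so depth does not account for it. A single WT p210 library carried 70% or more of the summed WT p210 CPM for 10.3% of the lower genes (53 of 517). Of the 517, 275 averaged under 1 CPM in KO p210, and of the 128 higher genes 19 averaged under 1 CPM in WT p210. In untransformed lines 147 of the 517 were lower in KO as well. Loss of Cdk6 and differences between the lines were not separated.

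In groups of 4 libraries, 11 of 206 tests found a library far from the rest (gap to the nearest library over the range of the group, against Dixon's 95% critical value), where chance gives 10.3. All 11 were in KO p210 and none in WT untransformed, the other group of 4. The 10.3 covers both groups, so it is not the value for KO p210 alone. It also takes the tests to follow Dixon's rate, which a ratio fixed by low counts does not. In Ccl8 (gap over range 1), Tceal8 (1), Kcnk12 (1) and Aqp1 (1) a single library had counts, 1 count in all but Tceal8, which fixes the ratio at 1 and does not show a library apart. In Oasl2 (0.833) and Rtp4 (0.833) replicate 4 had no counts and the others 2 or 3. Replicate 1 stood apart in Lrmda (0.861), Gata1 (0.858) and Gbp3 (0.892). Replicate 3 stood apart in the mean of the apoptosis regulators (0.867).

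The genotype effect differed between states, by the interaction term, for Slc43a1 (-4.41), Nxpe5 (-2.08), Arhgef5 (-7.33), Ifitm2 (-0.76) and Tceal8 (-7.01), as log2 fold changes. The fitted value of Arhgef5, with 2 counts in KO p210, depends on the prior count. That of Tceal8, with counts in only KO p210 replicate 4 of its group, is also uncertain in size. By camera it differed for DNA replication genes (adjusted p = 0.000199), mitosis genes (9.86e-13), adhesion genes (0.0406), stem and progenitor markers (0.0109), neutrophil and monocyte genes (0.000605), lymphoid genes (0.00431), interferon response genes (1.81e-13), receptors (6.38e-05), the integrated stress response (0.00445) and stromal markers (0.0102). With an estimated correlation the adjusted p of these lists was 0.205 to 0.692. The effect was higher in p210 for DNA replication, mitosis and integrated stress genes and lower for the other lists. The stem and progenitor call was lost without KO untransformed replicate 3 (0.0526) or WT p210 replicate 2 (0.0899), that of the integrated stress list without WT p210 replicate 3 (0.0674). That of stromal markers was lost without WT p210 replicate 3 (0.0569) or KO p210 replicate 4 (0.0823). The adhesion call was lost without KO untransformed replicate 2 (0.0513) or 3 (0.0526), WT p210 replicate 2 (0.243) or 3 (0.15), or KO p210 replicate 1 (0.061), 3 (0.0993) or 4 (0.053). With line as a block the adjusted p was 0.0976 for stem and progenitor markers and 0.162 for adhesion genes. Of 100 splits of the samples, 7 gave as many interaction genes as the real one, which is among them and gave 5. Of the 6 others, 3 keep the real genotype groups of the untransformed libraries, among them the highest (1256), and 1 keeps those of the p210 libraries, so the genotype effect of that state enters their counts. The other 2 are among 93 splits that keep the real genotype groups of neither state, and the highest count among those was 8. A grouping without the real genotype groups could thus give more than 5 genes, and chance is not excluded for the 5.

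For the other comparisons, 1 of 35 splits gave as many genes, the real one itself. This is a share under 0.05, the smallest that 35 splits can give, and it holds only if lines are ignored and libraries are taken as exchangeable. This does not exclude differences between the lines, and with only the p210 libraries in the fit KO against WT p210 gave 5 genes. The counts were 2211 for KO against WT untransformed (highest other 1257) and 645 for KO against WT p210 (highest other 188). For p210 against untransformed they were 5727 in WT (highest other 2142) and 5395 in KO (highest other 1820). Among the 8 splits that part 3 lines as the real one does, the highest other count was 0 in WT and 366 in KO, and 8 splits are too few for a share under 0.05. Splits that follow the code gave 0, 0, 2 and 0 genes in edgeR, with 985, 1830, 1321 and 664 at an unadjusted p under 0.05. Such splits mix genotypes or states within a group, so the real effects widen the spread. They therefore do not show whether the code had an effect.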

How the results depend on the processing

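The fit without both WT untransformed replicate 3 and the library labelled KO p210 replicate 2 was chosen only after the results had been seen. Of 4345 values of named genes under alternatives, 3885 kept direction and side of the threshold and 460 lost their call. Of 3822 for lists, 3534 kept both, 144 lost and 136 gained a call and 8 changed direction. The cause was not tested for the changes below, except where fewer libraries entered or the threshold itself was moved. With at least 2-fold, counts were 718 for KO against WT untransformed, 2177 for p210 against untransformed in WT and 2224 in KO. Under adjusted p 0.01 they were 358, 159 (KO against WT p210), 3453, 3121 and 0 for the interaction (2041 unadjusted in edgeR). Without a filter 1273 genes were called for KO against WT untransformed. Library size scaling gave 3 interaction genes. DESeq2 gave 3499 and 1454 for the KO against WT comparisons and 409 for the interaction. In simulated counts 38 of its 162, 29 of 149 and 36 of 121 calls were false, shares that cannot be carried over to the real calls. Limma-voom gave 386 for KO against WT p210 and 4 for the interaction. With only the groups compared, counts were 3399 (untransformed) and 5 (p210). Sequencing runs as a covariate gave 1042, 421, 3652 in WT, and 0 for the interaction (1124 unadjusted). Replicate numbers did not pair genotypes (deviations correlated at -0.0814 to 0.119 for the same number and -0.213 to 0.265 for other numbers). The replicate block gave 366 for KO against WT p210 and 0 for the interaction (1847 unadjusted), and 1632, 5001 and 4909 elsewhere. Line as a block gave 3586 in KO, 3828 in WT and 0 for the interaction (1142 unadjusted). It ended the calls of Cdk6 in WT, Plk1 in KO, and the adhesion and megakaryocyte lists in WT. It changed no other call of a gene named for the transformation comparisons. It gave calls to the cholesterol list in both genotypes and to the dendritic cell, inflammatory and apoptosis lists in KO, whose adjusted p without the block was 0.386 to 0.824 with an estimated correlation, and to the MAPK list in the interaction (0.00546; without the block 0.217, and adjusted p = 0.692 with an estimated correlation). With fry, which tests whether members move one way on balance, lists that lost their call were megakaryocyte (0.0955), dendritic (0.0593) and interferon genes (0.0771) for KO against WT untransformed, and neutrophil (0.578), megakaryocyte (0.126), interferon (0.0702), inflammatory (0.623) and integrated stress genes (0.126) for p210. Mitosis (0.0603) and megakaryocyte genes (0.0509) lost it for p210 in WT, as did 7 interaction lists (up to 0.343). Fry, which does not compare a list with other genes, also called 12 lists that camera did not: G1 regulators in KO against WT (0.00128 untransformed, 0.0104 p210) and with p210 (0.000213 in WT, 8.1e-05 in KO), mast cell, lymphoid, stromal and BCR-ABL partner genes with p210 in WT, and dendritic, BCR-ABL partner, oxidative phosphorylation and apoptosis genes in KO (up to 0.022). Code as a covariate gave 0 interaction genes (1912 unadjusted). The first code alone gave 435, 3725 in WT and 32 for the interaction. The second code alone gave 0 (2466 unadjusted), 4, 1566, 73 and 0 (1617 unadjusted), with Cdk6 at -2.45 (adjusted p = 0.236) in untransformed lines. Without both doubted libraries counts were 920, 275 and 0 (1440 unadjusted), and Cdk6 in p210 was -1.28 (adjusted p = 0.0209). With the first code alone 12 list calls were lost. These were dendritic, lymphoid and megakaryocyte genes for KO against WT untransformed, and integrated stress, neutrophil and stromal genes for p210. Adhesion, megakaryocyte, mitosis and oxidative phosphorylation genes lost theirs for p210 in WT, and adhesion and lymphoid genes in the interaction. Lists that changed direction were, for the first code, mitosis in p210 (adjusted p = 0.00233) and megakaryocyte (2.97e-07) and stromal genes (0.954) in the interaction. For the second code they were megakaryocyte (0.977), inflammatory (0.323) and cholesterol genes (0.000957) in p210 and inflammatory (0.0127) and cholesterol genes (0.0208) in the interaction. Leaving out 1 library gave 181 to 2643 and 285 to 736 genes for KO against WT, 4668 to 5854 and 3969 to 5742 for transformation in WT and KO, 0 to 46 for the interaction. Cdk6 ranged from -2.24 to -2.09 (untransformed) and from -1.28 to -0.63 (p210). Where a removal or a code left a group with 1 library, that library was assumed to vary like the others. Genes called for genotype in the same direction in both states numbered 217, 108 among genes above the median level and 250 with code as a covariate. The first component held 48.4% of the variance over all genes, against 62.1%. RLE and upper quartile scaling, a stricter filter and leaving out X and Y genes kept each count of called genes within 1.5 times. In simulated counts for the interaction, edgeR recovered 5.97% of 1.5-fold and 31.3% of 2-fold changes. At this depth, 3 counts over a group corresponded to 0.0198 to 0.0369 CPM, below which no level was resolved.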

Other observations

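The test of whole chromosomes was chosen only after the results had been seen.

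Of 24 MAPK feedback and immediate early genes, 6 fell and 1 rose in KO untransformed against WT (8 and 2 adjusted over the list alone; camera adjusted p = 0.0916), and Fos was the one that rose (2.04 ± 0.48, from 8.88 to 36.4 CPM). The call of Fos was lost without WT untransformed replicate 4 (adjusted p = 0.0582) or KO untransformed replicate 1 (0.065) or 2 (0.109), and in 3 other alternatives (up to 0.524). With p210 in WT 5 of the MAPK genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.564). In KO p210 against KO untransformed 8 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.176). Of 20 BCR-ABL partner and adaptor genes, 8 rose and 5 fell with p210 in WT, also adjusted over the list alone (0.144), and 6 rose and 3 fell in KO (9 and 4 adjusted over the list alone; 0.0572). Of 30 oxidative phosphorylation genes, 10 fell with p210 in WT, where 39.5% of all genes passed, also adjusted over the list alone, with camera adjusted p = 0.0121 (adjusted p = 0.609 with an estimated correlation; 0.0624 without WT p210 replicate 3), and 8 fell in KO (8 adjusted over the list alone; 0.0645). Of 24 cholesterol synthesis genes, 2 fell in WT and 3 in KO, of which 2 in KO also passed adjusted over the list alone (camera adjusted p = 0.125 and 0.051; 0.00795 and 0.000331 with line as a block; adjusted p = 0.800 and adjusted p = 0.816 with an estimated correlation and no block). Of 31 glycolysis and hypoxia genes, 6 rose and 4 fell in WT and 4 rose and 5 fell in KO, the same adjusted over the list alone (0.522 and 0.89). The integrated stress list was called up in KO p210 against KO untransformed, where 8 of 22 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00978; adjusted p = 0.42 with an estimated correlation); in WT 7 rose and 4 fell, also adjusted over the list alone (0.486). Receptor genes were called down there, with 11 of 24 lower and 3 higher, also adjusted over the list alone (0.00635; adjusted p = 0.253 with an estimated correlation), and in WT 6 rose and 7 fell, also adjusted over the list alone (0.615).

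Genes of other lineages moved in part. Of 16 lymphoid genes, 2 rose in KO untransformed against WT (2 adjusted over the list alone; camera adjusted p = 0.0139; adjusted p = 0.343 with an estimated correlation), and 6 rose and 1 fell with p210 in WT, also adjusted over the list alone (0.341). With p210 in KO 2 lymphoid genes rose and 4 fell, also adjusted over the list alone (camera direction down, 0.691), with a median log2 fold change of 0.20 and a mean of -0.23. The 12 dendritic cell and MHC class II genes were called up in KO untransformed (0.0356; adjusted p = 0.49 with an estimated correlation), although 0 of the 12 genes passed in edgeR (7 at an unadjusted p under 0.05; 3 passed in DESeq2 and 7 in limma-voom). The call was lost without KO untransformed replicate 2 (0.0797) or 3 (0.075), WT untransformed replicate 3 (0.0583) or WT p210 replicate 2 (0.0814) or 3 (0.0825). In KO p210 against KO untransformed 4 of these 12 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.051; 0.0386 with line as a block; adjusted p = 0.572 with an estimated correlation and no block), and in WT 2 rose and 2 fell, also adjusted over the list alone (0.477). Of 24 inflammatory genes, 9 rose and 1 fell with p210 in WT (0.311) and 9 rose and 2 fell in KO (0.226; 0.0268 with line as a block; adjusted p = 0.824 with an estimated correlation and no block), also adjusted over the list alone. They were called up in KO p210 against WT p210 (0.0408; adjusted p = 0.881 with an estimated correlation), which was lost without WT p210 replicate 2 (0.437) or 3 (0.079) or KO p210 replicate 1 (0.424), or without the library labelled KO p210 replicate 2 (0.266). Of 9 stromal and endothelial markers, 2 fell in KO p210 against WT p210 (3 adjusted over the list alone, beside 1 that rose; camera adjusted p = 0.0161; adjusted p = 0.357 with an estimated correlation), a call lost without WT p210 replicate 3 (0.0888) or KO p210 replicate 3 (0.0508) or 4 (0.0922). In KO p210 against KO untransformed 4 of these 9 fell and 1 rose (5 and 1 adjusted over the list alone; 0.00897; adjusted p = 0.211 with an estimated correlation; 0.0552 without KO p210 replicate 4), and with p210 in WT 2 rose and 3 fell, also adjusted over the list alone (0.307). Of 6 eosinophil genes 1 rose with p210 in WT, a call lost when adjusted over the list alone (0.615), and 1 rose and 1 fell in KO, also adjusted over the list alone (0.704). Of 11 genes linked to CDK6 as a transcriptional regulator, 1 rose in KO in each state, also adjusted over the list alone (0.877 and 0.986), and with p210 3 rose and 3 fell in WT and 3 rose and 4 fell in KO, also adjusted over the list alone (0.589 and 0.704). Of 4 sex-linked transcripts, 2 rose with p210 in each genotype (2 in WT and 3 in KO adjusted over the list alone), and of 9 replication-dependent histone genes 2 rose and 1 fell with p210 in WT, also adjusted over the list alone.

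With all libraries thinned to the same total, 18816 ± 291 genes were detected in WT p210 (SD, n = 3) and 18078 ± 119 in KO p210 (n = 4), a difference of 737 genes. The two-sided exact permutation p was 0.0286, the smallest that 3 against 4 libraries can give here.

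Gain or loss of a whole chromosome could move many genes at once in a cultured line. Each gene was set against its median over the 14 libraries. Over 9821 genes, the largest absolute median log2 ratio of an autosome in any library was 0.0874 (-0.09, chromosome 9, WT untransformed replicate 3). The ratio is 0.58 for 3 copies in place of a pair, so a whole-chromosome change in most cells of some libraries but not others was not seen. A change shared by all 14 libraries would leave no ratio and could not be seen.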
